A study of Bos taurus with 19 samples.

How the data were processed

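Liver RNA of 19 growing beef steers (Bos taurus) was measured on 1 Affymetrix bovine expression array per steer. Of these steers, 10 had grazed a pasture of tall fescue with a high level of toxic endophyte (HE) and 9 a pasture with a low level (LE), each for 88 days on 5.7 ha. A toxic endophyte is a fungus living inside the grass that makes ergot alkaloids. Per the labels' protocols, about 2 g of the right liver lobe was taken, total RNA was extracted with TRIzol, and biotinylated cRNA was made from 4 µg of it. The labels disagree on whether the LE sward was tall fescue alone or mixed with other grass, and on whether liver was taken by biopsy or after death; neither is settled here. They give no array batch, hybridisation date or scan date, so none could be tested.

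The authors deposited a table of log2 expression values, with 1 value per probe set and array. The submitters' processing notes name GCOS 1.2 and Partek 6.4 without their roles. The normalization and background correction were not given in the sources used here. The array medians lay between 5.20 and 5.28 on the log2 scale, and the distributions of the 19 arrays nearly coincided, so the deposited values had been normalized between arrays and were used as they stood. The table holds no detection calls, and dim probe sets pile up near a floor, where differences are compressed. For arrays, the number of steers limits the precision; the median standard error of a log2 difference was 0.0823 over probe sets and 0.0911 over genes.

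The 112 control probe sets were left out of the tests, which left 24016. Gene names came from the platform annotation supplied with the data, which named 1 gene for 13292 of the tested probe sets, several for 86 and none for 10638. Symbols were updated through Entrez gene numbers in a RefSeq gene table of assembly ARS-UCD2.0, in which 13283 of the 13318 annotated probe sets with 1 gene (controls included) were found. That table was used for names only, so no coordinates are given. Each of 9155 genes was represented by its probe set with the highest mean over all arrays; 2913 genes had more than 1 probe set.

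Differences were taken as HE minus LE on the log2 scale and tested 2-sided with limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets or all genes. The threshold was an adjusted p of 0.05. Errors printed after ± are standard deviations between steers, and standard errors are those of limma. Gene lists were tested with camera, a limma test of whether the members of a list shift relative to all other genes, with its preset correlation between genes of 0.01. The lists, 47 in number, covered hepatic metabolism, stress responses, protein synthesis, hormone axes, markers of the cell types that a piece of liver can hold and the state of the sample. The list of mitochondrially encoded transcripts had 0 measured members and was not tested, which left 46 lists; the smallest size allowed was 5. The same lists were run with camera's estimated correlation and with fry, which asks whether the members move one way on balance and makes no comparison with other genes. A list score is the mean over members of each steer's log2 value minus the mean of all steers. Principal components of all tested probe sets, and the 3' minus 5' log2 difference of the actin and GAPDH control probe sets, were compared between groups by exact 2-sided permutation tests over all 92378 assignments. Permutations, exact tests and tables were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

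The groups, tests, gene lists, other settings to be tried and the rule for naming genes were fixed before the data were examined. Under that rule, because fewer than 5 genes passed the threshold, the 10 highest and 10 lowest by moderated t are named as not past it. To these are added the 4 members with the smallest p of each list past the threshold, at most 2 of each other list, and a fixed set of metabolic, endocrine and ergot-target genes. Of that fixed set, TFAM, CYP3A4 and CYP3A5 were not analysed here, and 1 other gene is not reported here. The text gives a selection of the genes that the rule names. The probe set past the threshold, BOLA-DQ probe sets, SERPINI2, PRSS2, GPX3, FKBP5, XDH and C6H4orf19 fall outside the rule and were chosen after their values were seen. Lists on serine, proline, ATP synthesis and mitochondria cover themes that the study is known to have reported from these same steers.

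Alternatives covered filters on dim probe sets, quantile normalization, median centring, other variance models, a one-way ANOVA without moderation, array weights, covariates, the mean of all probe sets of a gene, other thresholds and set tests, and leaving out each steer. An exact permutation of list scores was added after the data had been seen. Alternatives planned for linear values were not run, because the values are log2. The procedure was tested on simulated data for this comparison. Over 9155 genes it recovered 67.5%, 95% and 100% of genes changed by 0.5, 1 and 2 log2 units, with 6 false among 176 calls. Over 24016 probe sets the shares were 46.25%, 92.5% and 95%, with 6 false among 155 calls. In 46 simulated lists, both lists shifted by 0.2 log2 units were found, and 1 other was called. Simulated genes varied independently of one another, and changes to single genes or probe sets were placed only above the median brightness. These results therefore do not carry over to dimmer genes, to genes that vary together or to other numbers of changed genes. In the real data, random splits of the steers called a median of 11 lists.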

Results

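The data are hepatic expression profiles of 19 steers, each measured on 1 array of 24016 tested probe sets that represent 9155 named genes. The HE group (n = 10) grazed tall fescue carrying much toxic endophyte, and the LE group (n = 9) grazed a pasture low in it, for 88 days. The labels leave open whether the LE sward also held other grass. Each group grazed a single pasture, so pasture and group cannot be told apart, and p-values measure the spread between steers that grazed together. The comparison asks how hepatic transcript levels differ between steers on these pastures.

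Genes of serine and proline synthesis and an IGF-binding protein were among the 10 highest genes by moderated t. PYCR1, which makes proline, averaged 7.19 ± 0.800 in HE (SD, n = 10) and 5.50 ± 1.18 in LE (SD, n = 9), a 3.24-fold difference with a log2 standard error of 0.430. PSPH, the last enzyme of serine synthesis, was 2.95-fold higher (log2 1.56, SE 0.400), and IGFBP1, a hepatic protein that binds IGF1, was 3.23-fold higher (log2 1.69, SE 0.430). TMED6, a member of the family of vesicle transport proteins, was 3.30-fold lower (log2 -1.72, SE 0.314). All 10 HE steers lay above the LE mean for PYCR1 and IGFBP1 and 9 did for PSPH, while all 10 lay below it for TMED6. None of the 9155 genes passed limma's adjusted threshold, so these are values and not calls. The smallest adjusted p, 0.0868, was shared by TMED6, the chemokine receptor CXCR6 (log2 -0.68) and GUCY1B1, a subunit of soluble guanylate cyclase (log2 -0.46). These 3 genes passed at an adjusted p of 0.10.

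At an unadjusted p under 0.05, 797 genes differed (402 higher and 395 lower in HE), against 457.75 expected by chance on average. How far this count varies by chance was not tested. The same linear model without moderation of the variance also called 0 genes. The 10 highest also held PHF13 (log2 0.55), PDE8A, a cyclic AMP phosphodiesterase (0.38), RBPMS (0.55), the complement receptor CR2 (0.60), HAX1 (0.40) and the ribosomal protein genes RPS16 (0.21) and RPL10A (0.31). The adjusted p of these 10 genes ran from 0.286 to 0.318. The other genes among the 10 lowest were SERPINE2, a protease inhibitor (-0.73), APOLD1 (-0.96), AP1S2 (-0.44), BCL2A1, an inhibitor of cell death (-0.73), the vitamin E-binding plasma protein AFM (-0.42), PLXNC1 (-0.37) and the lymphoid cytokine LTB (-0.62). SERPINE2 had an adjusted p of 0.108 and APOLD1 of 0.162. With array weights TMED6, GUCY1B1 and SERPINE2 passed. Single omissions also carried genes past the threshold: GUCY1B1 and CXCR6 without HE steer 6 (2 genes), APOLD1 and C6H4orf19 without LE steer 12 (2 genes), TMED6, CXCR6 and GUCY1B1 without LE steer 14 (3 genes), and SERPINE2 without LE steer 18 (1 gene).

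A single probe set passed limma's threshold over all 24016. It has no gene listed, its identifier stands in the title of the plot of its values, and it fell by 2.92 on the log2 scale in HE (SE 0.286, 95% interval -3.51 to -2.32, adjusted p = 6.74e-05), 7.54-fold lower. HE steers averaged 3.54 ± 0.484 (SD, n = 10) and ranged from 2.93 to 4.31, and LE steers averaged 6.46 ± 0.819 (SD, n = 9) and ranged from 5.48 to 7.99. The groups did not overlap. The next adjusted p was 0.146. At an unadjusted p under 0.05, 1571 probe sets differed (692 higher and 879 lower), against 1200.8 expected on average. Of 100 splits of the steers, the real one included, 13 gave at least as many. The count of 1 became 0 under a filter at the median brightness, which leaves this probe set out, and reached 2 without LE steer 4, 3 without LE steer 12, 7 without LE steer 14 and 2 without LE steer 18.

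**Figure D1:**
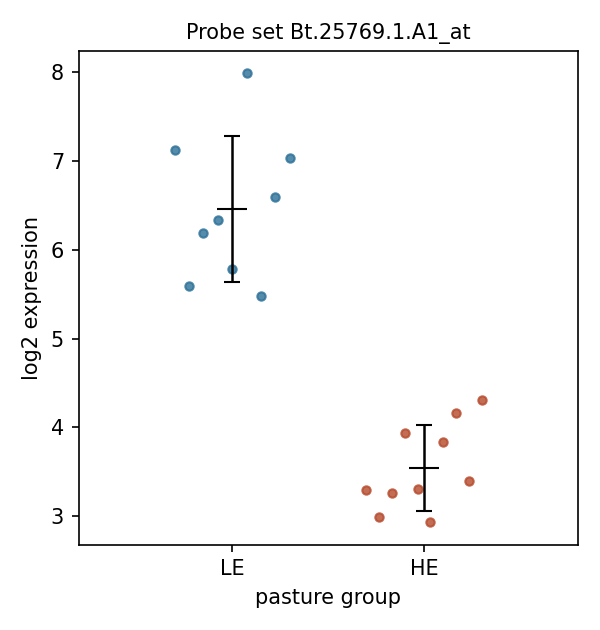
Expression (log2) of the probe set past the threshold in each LE (n = 9) and HE (n = 10) steer; points are steers, the long bar is the mean and the whiskers are 1 SD. HE steers lie between 2.93 and 4.31 and LE steers between 5.48 and 7.99.

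Of 46 gene lists, 16 passed camera, 10 higher and 6 lower in HE. This count does not argue against chance. Of 100 splits of the steers, the real one included, 21 gave at least 16 lists, and the other 99 gave a median of 11. Only the T and NK cell marker list passed with an estimated correlation, and the same list alone passed fry. An exact permutation of list scores, chosen after the data were seen, also called 1 list, the T and NK cell list.

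**Figure D2:**
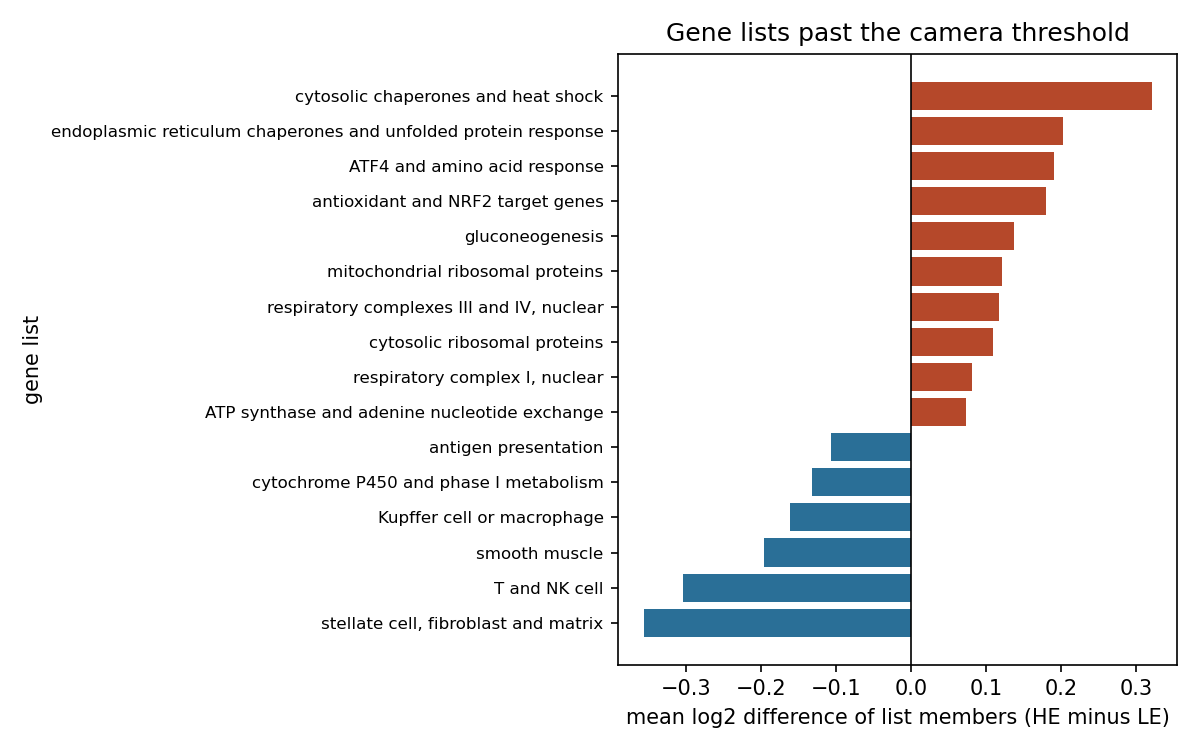
Mean log2 difference (HE minus LE) over the measured members of each of the 16 lists past camera; each bar is 1 list, red bars are higher in HE and blue bars lower. Bars run from -0.36 for stellate cell, fibroblast and matrix markers to 0.32 for cytosolic chaperones.

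Markers of T and NK cells, the lymphocytes resident in and passing through the liver, were lower in HE. The list fell by 0.31 on the log2 scale on average (19 genes, camera adjusted p = 3.48e-11), with 18 members lower and 1 higher. Its adjusted p was 0.0229 with an estimated correlation and 0.00600 by fry, and its score gave an exact permutation p of 0.000455 (adjusted p = 0.0209). List scores averaged -0.144 ± 0.0949 in HE (SD, n = 10) and 0.161 ± 0.219 in LE (SD, n = 9). Adjusted over the list alone 10 members were lower, and over all genes 0. The T cell kinases ZAP70 (log2 -0.58, SE 0.144) and LCK (-0.51, SE 0.129) and the T cell receptor chain CD3G (-0.46, SE 0.115) each had an adjusted p over the list alone of 0.00504. The adhesion receptor CD2 differed by -0.42 (0.0114 over the list alone). All 10 HE steers lay below the LE mean for each of these 4 genes. Of the 19 markers, 7 were at or above the brightness of the median probe set and 0 belonged to another list.

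Some other non-parenchymal markers pointed the same way without holding under an estimated correlation. The stellate cell, fibroblast and matrix list fell by 0.36 (20 genes, 18 lower, camera adjusted p = 2.10e-07; adjusted p = 0.386 with an estimated correlation), and 5 members passed adjusted over the list alone and 0 over all genes. These included the collagen genes COL1A2 (log2 -1.32, SE 0.398) and COL4A1 (-0.29, SE 0.0868), the matrix protein gene SPARC (-0.48) and the filament gene VIM (-0.48), each with an adjusted p over the list alone of 0.0271. LE steer 19 had the highest score of the stellate list (0.87) and a far value of COL1A2 (10.8). The list passed camera in all 19 omissions of a steer, with a mean from -0.42 to -0.27. Its score gave an exact permutation p of 0.00843 (adjusted p = 0.111). Kupffer cell or macrophage markers fell by 0.16 (12 genes, 11 lower, camera adjusted p = 0.00487; adjusted p = 0.514 with an estimated correlation), with TYROBP at -0.28 and CD68 at -0.20. Smooth muscle markers fell by 0.20 (9 genes, all lower, camera adjusted p = 0.0164; adjusted p = 0.417 with an estimated correlation), with CNN1 at -0.15 and TAGLN at -0.39 (-0.24 without HE steer 2). Antigen presentation genes fell by 0.11 on average and 0.20 at the median (16 genes, 14 lower, camera adjusted p = 0.0115; adjusted p = 0.514 with an estimated correlation). In that list the MHC class II genes BOLA-DRA and BOLA-DRB3 stood at -0.30 and -0.31, though the second probe set of BOLA-DRB3 had the opposite sign. The class II gene BOLA-DMB stood at -0.43 and BOLA-DQA1 the other way at 0.81 (SE 0.389). The list also holds BOLA-DQB, of which a probe set was high only in LE steers 5, 7 and 19 and HE steer 16. Its values were 6.36 to 8.58 in those steers and 1.75 to 1.84 in the rest. How far this gene carries the mean of the list was not tested. In these last 3 lists 0 members passed adjusted over the list alone or over all genes. The stellate, Kupffer and smooth muscle lists each share 1 gene with another list.

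Omission of single steers ended some of these calls. The antigen presentation list gave adjusted p = 0.0574 without LE steer 7 and 0.0514 without LE steer 19, and 0.0798 with the mean of all probe sets of a gene. Its mean of -0.11 also moved widely: to -0.011 with the mean of all probe sets, -0.059 with the filter at the median brightness, -0.025 without LE steer 19, -0.048 without LE steer 5, -0.065 without LE steer 13, -0.068 without LE steer 8, -0.17 without HE steer 6 and -0.23 without LE steer 4. The Kupffer cell list gave 0.0530 without LE steer 7. The smooth muscle list gave 0.0549 without HE steer 2, 0.0713 without LE steer 7, 0.0556 without LE steer 12 and 0.0583 with array weights. Over all alternatives the adjusted p ran from 0.000164 to 0.514 for antigen presentation, 0.000138 to 0.514 for Kupffer cells and 0.00251 to 0.417 for smooth muscle.

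Marker lists of other cells did not pass camera. Adjusted p was 0.675 for B and plasma cells, 0.826 for hepatocytes, 0.249 for endothelial cells, 0.101 for neutrophils, 0.0833 for cholangiocytes (0.0192 with array weights, range 0.0192 to 0.738) and 0.374 for erythroid cells and blood. The B and plasma cell list had a mean of 0.016 and a median of 0.0048 while the test pointed down. The albumin gene ALB stood at 16.5 ± 0.0398 in HE (SD, n = 10) and 16.5 ± 0.0541 in LE (SD, n = 9), at the top of the scale of the arrays (highest values 16.41 to 16.58), so this probe set says little about a difference. Of its 8 other probe sets, 4 had the opposite sign. The apolipoprotein gene APOA1 differed by 0.14 (0.026 without HE steer 2, 0.22 without HE steer 11, 0.091 without LE steer 14).

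**Figure D3:**
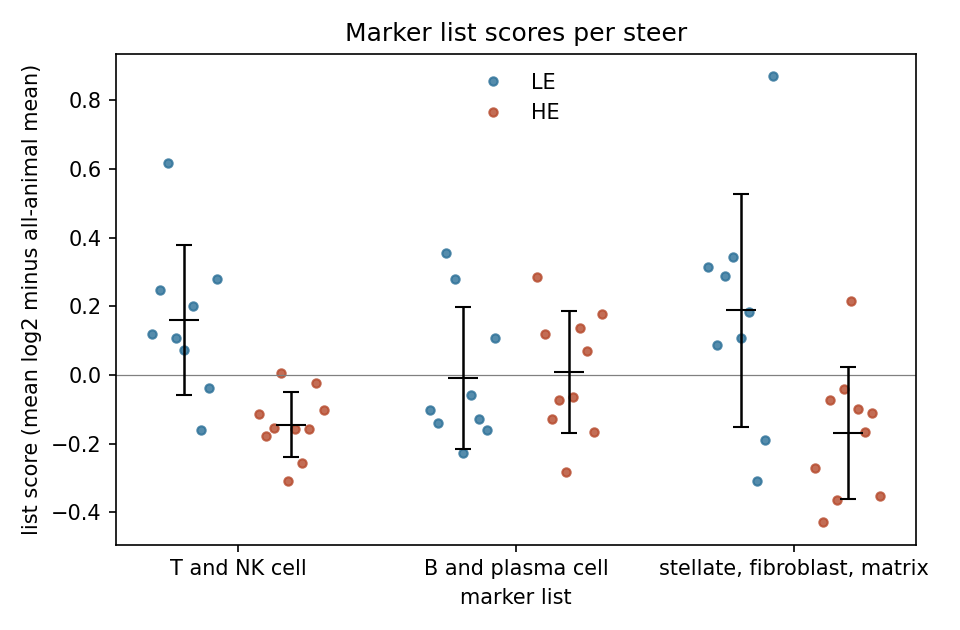
List scores (mean log2 value minus the mean of all steers) of T and NK cell, B and plasma cell, and stellate cell, fibroblast and matrix markers in each LE (n = 9) and HE (n = 10) steer; points are steers, the long bar is the mean and the whiskers are 1 SD. T and NK cell scores average -0.144 in HE and 0.161 in LE.

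Of the lists on amino acids, 1 passed camera. The ATF4 and amino acid response list, targets of a transcription factor active in amino acid shortage, rose by 0.19 (21 genes, 15 higher, camera adjusted p = 0.00207; adjusted p = 0.398 with an estimated correlation). One member, the translation repressor gene EIF4EBP1 (log2 0.29), passed adjusted over the list alone (0.0271) and 0 over all genes; ATF5 differed by 0.52, and 6 of the 21 genes also belong to another list. The serine, glycine and one-carbon list did not pass (adjusted p = 0.0647; past the threshold with the 3' to 5' covariate, 0.0417, in a range from 0.0186 to 0.468), and PSPH alone of its 23 genes passed adjusted over the list alone (0.0212), with 0 over all genes. PHGDH, the first enzyme of serine synthesis, differed by 0.66 (SE 0.215) and PSAT1, the enzyme between them, by 0.10 (SE 0.107; 0.018 without LE steer 14). The proline, glutamate and glutamine list did not pass (adjusted p = 0.146), yet adjusted over the list alone 6 of its 18 genes were higher and 2 lower, and 0 over all genes.

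Within the proline list, PYCR1 and ALDH18A1 (log2 0.52), both of proline synthesis, and the transaminase genes GPT2 (0.80) and GOT1 (0.34) were among those higher. PRODH, the first enzyme of proline breakdown, was lower (-0.74, SE 0.189), with the same adjusted p over the list alone as PYCR1, 0.00792. Its means of 3.82 in HE and 4.56 in LE lay below the median probe set (5.28). ALDH4A1 differed by -0.13 (-0.086 without HE steer 2, -0.20 without HE steer 10), GLUL by -0.11 (-0.073 without LE steer 7, -0.041 without LE steer 18, -0.17 without LE steer 19) and GOT2 by 0.031, and GPT lay near the floor at 2.18 ± 0.0256 in HE (SD, n = 10). Serine and proline are themes that the study is known to have reported from these steers, so these counts are not independent evidence. Amino acid transporters gave an adjusted p of 0.0833, the urea cycle 0.529 and amino acid catabolism 0.925, the last with a test pointing up and a mean of -0.016.

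**Figure D4:**
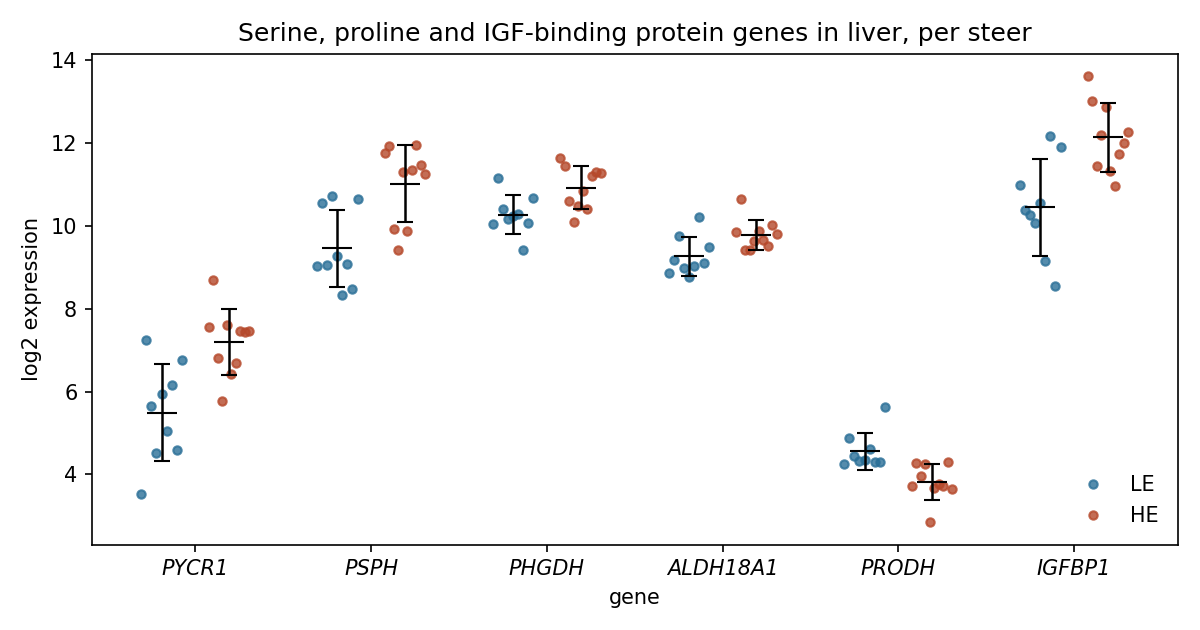
Expression (log2) of PYCR1, PSPH, PHGDH, ALDH18A1, PRODH and IGFBP1 in each LE (n = 9) and HE (n = 10) steer; points are steers, the long bar is the mean and the whiskers are 1 SD. The PYCR1 means are 7.19 in HE and 5.50 in LE, and the groups overlap for every gene shown.

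Gluconeogenesis genes, which include the transaminases above, rose by 0.14 on average (16 genes, 12 higher, camera adjusted p = 0.0365; adjusted p = 0.386 with an estimated correlation). GPT2 alone passed adjusted over the list alone (0.0353), and 0 genes over all genes; 7 of the 16 genes also belong to another list. The dedicated enzymes stood at log2 -0.22 for PCK1 (SE 0.156; -0.12 without HE steer 9), 0.33 for PC (SE 0.186; 1 of 2 other probe sets opposite in sign), 0.18 for FBP1 (SE 0.154; 0.12 without HE steer 2, 0.089 without LE steer 8) and 0.023 for G6PC1 (SE 0.282), the last turning negative with array weights (-0.11). The call ended without HE steer 1 (0.0645), HE steer 10 (0.0575), LE steer 14 (0.0557), HE steer 15 (0.103) or LE steer 18 (0.121). It also ended under 6 other settings of the fit, among them quantile normalization (0.0784) and median centring (0.0720), and over all alternatives the adjusted p ran from 0.0150 to 0.386. Glycolysis (adjusted p = 0.938) and the TCA cycle (0.550) did not pass; the glycolysis test pointed up against a mean of -0.017.

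Genes of protein synthesis and mitochondrial respiration had small mean differences, higher in HE. Cytosolic ribosomal protein genes rose by 0.11 (61 genes, 59 higher, camera adjusted p = 1.08e-20; adjusted p = 0.386 with an estimated correlation), and 9 passed adjusted over the list alone against 0 over all genes. Examples are RPS16 (log2 0.21, SE 0.0505), RPL10A (0.31, SE 0.0809), RPL29 (0.25) and RPS10 (0.19). Mitochondrial ribosomal protein genes rose by 0.12 (65 genes, 58 higher, camera adjusted p = 4.25e-11; adjusted p = 0.386 with an estimated correlation), led by MRPL37 (0.37) and MRPS22 (0.25), with 0 members past either adjustment.

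Nuclear genes of respiratory complex I, which takes electrons from NADH, rose by 0.081 (37 genes, 34 higher, camera adjusted p = 2.78e-06; adjusted p = 0.468 with an estimated correlation). NDUFV2 (log2 0.21), NDUFC1 (0.22) and NDUFA5 (0.29; 1 of 2 other probe sets opposite in sign) passed adjusted over the list alone (0.0384 each) and 0 over all genes. Complexes III and IV rose by 0.12 (18 genes, all higher, camera adjusted p = 2.58e-06; adjusted p = 0.417 with an estimated correlation), with COX5A at 0.28. ATP synthase and adenine nucleotide exchange rose by 0.073 (24 genes, 21 higher, camera adjusted p = 5.04e-05; adjusted p = 0.417 with an estimated correlation), with ATP5F1D at 0.14 and SLC25A6 at 0.23, though all other probe sets of these genes had the opposite sign. In these last 2 lists 0 members passed adjusted over the list alone or over all genes. Mitochondrial biogenesis did not pass (adjusted p = 0.102; 0.0469 with the first residual component as covariate, range 0.0376 to 0.546); its chaperone gene HSPA9 (0.37; opposite in its second probe set) passed over the list alone (0.0494) and PPARGC1A, a coactivator of mitochondrial genes, differed by 0.17 (SE 0.213; 0.079 to 0.28 over single omissions of HE steer 1 or LE steers 12, 13 and 19). Lists on ATP synthesis and mitochondria take up themes the study is known to have reported from these steers and are not independent evidence. The proteasome (adjusted p = 0.0743) and cell cycle (0.185) lists did not pass.

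Chaperone and antioxidant genes were also higher in HE as lists. Cytosolic chaperones and heat shock genes, which refold proteins, rose by 0.32 (22 genes, all higher, camera adjusted p = 1.83e-07, and 0.417 with an estimated correlation). HSP90AB1 stood at 0.32 and HSPE1 at 0.21. HSPE1 is also in the mitochondrial biogenesis list, and 2 of the 22 genes belong to another list. Endoplasmic reticulum chaperones and the unfolded protein response rose by 0.20 (24 genes, 23 higher, camera adjusted p = 0.00140; adjusted p = 0.630 with an estimated correlation), with SEL1L at 0.24 and DERL2 at 0.22; its mean was 0.13 without LE steer 5 and 0.33 without LE steer 14. Antioxidant and NRF2 target genes rose by 0.18 on average and 0.053 at the median (31 genes, 21 higher, camera adjusted p = 0.0292; adjusted p = 0.406 with an estimated correlation). Its members moved apart: SRXN1 (log2 0.97), GSR (0.39), the metallothionein MT2A (1.48) and GCLC (0.53; 0.32 without LE steer 8 and 0.34 without HE steer 2) had positive values and the selenium carrier SELENOP a negative one (-0.14). In all 3 lists 0 members passed adjusted over the list alone or over all genes. The antioxidant call ended without HE steer 1 (0.0541), HE steer 6 (0.0525), LE steer 14 (0.0527) or LE steer 18 (0.126) and under 6 other settings of the fit, among them quantile normalization (0.0770) and median centring (0.0720). Over all alternatives its adjusted p ran from 0.00663 to 0.406.

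Cytochrome P450 and phase I genes, which oxidise drugs and alkaloids, fell by 0.13 on average (27 genes, 24 lower, camera adjusted p = 0.00143; adjusted p = 0.514 with an estimated correlation), with 0 members past the adjustment over the list alone or over all genes. CYP2E1 stood at log2 -0.26, CYP2C87 at -0.92 and the alcohol dehydrogenase ADH4 at -0.19. Over omissions of a steer the mean of the list ran from -0.20, without LE steer 14, to -0.091, with a camera adjusted p of at most 0.0347. The lowest list scores were those of LE steer 14 (-0.470) and HE steer 2 (-0.433). POR, the electron donor of the P450 enzymes, differed by -0.12 (SE 0.0895; -0.077 without HE steer 3, -0.067 without LE steer 18) and CYP3A28 by -0.096 (SE 0.334). Phase II conjugation (adjusted p = 0.805) and drug and bile transporters (0.374) did not pass, and in both the test and the mean differed in sign (means -0.0046 and 0.026). The ergot alkaloid target and biogenic amine list gave 0.201; DRD2 and ADRA2A, receptors of dopamine and noradrenaline, lay near the floor at 1.92 ± 0.0124 and 1.58 ± 0.0240 in HE (SD, n = 10), and the serotonin receptor HTR2B differed by -0.11 (SE 0.462).

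Lists of lipid, bile acid and endocrine genes did not pass camera, though 2 of them passed under other settings of the fit. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was 2.43-fold lower (log2 -1.28, SE 0.382) and passed adjusted over the list alone (0.0462) but not over all genes; its list gave an adjusted p of 0.0559. That list passed with median centring (0.0121), the filter at the median brightness (0.0138), quantile normalization (0.0220), the filter at the 25th percentile (0.0316) and the first residual component as covariate (0.0374), in a range over all alternatives from 0.00648 to 0.468. In the GH, IGF and prolactin axis (adjusted p = 0.961; test down, mean 0.018) 2 members were higher and 1 lower adjusted over the list alone, and 0 over all genes. These were IGFBP1 and IGFBP2 (log2 0.77), both at 0.0135, and the growth hormone receptor GHR (-0.53, at 0.0278), of whose 10 other probe sets 9 had the same sign. IGF1 itself differed by -0.89 (SE 0.387) and the prolactin receptor PRLR by -0.19 (SE 0.196), the last moving to -0.070 without HE steer 2, -0.12 without LE steer 8 and -0.30 without LE steer 14.

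Fatty acid oxidation gave an adjusted p of 0.0837, with the carnitine carrier SLC25A20 at -0.31. It passed with the filter at the median brightness (0.0202), median centring (0.0341) and the filter at the 25th percentile (0.0372), in a range from 0.0202 to 0.526. Fatty acid synthesis gave 0.529, lipoproteins 0.408 and cholesterol synthesis 0.826, where the test pointed down and the mean was 0.0030. Among the remaining lists the adjusted p was 0.540 for acute phase proteins, 0.805 for complement and coagulation, 0.266 for interferon-stimulated genes, 0.925 for the circadian clock and 0.351 for immediate early genes.

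The arrays separated weakly by group. The first 3 principal components held 21.3%, 10.3% and 7.97% of the variance. On the third, HE steers averaged -7.20 ± 11.7 (SD, n = 10) and LE steers 8.00 ± 11.1 (SD, n = 9), with an exact permutation p of 0.0103 (adjusted p = 0.0308); the first and second gave exact p values of 0.168 and 0.188. The call on the third component ended without HE steer 1 (0.229), LE steer 8 (0.0557), HE steer 9 (0.176), HE steer 10 (0.0698), LE steer 14 (0.0690), HE steer 16 (0.0842) or LE steer 18 (0.0618), in a range over all alternatives from 0.00284 to 0.229. The mean 3' minus 5' difference of the control probe sets, which grows as RNA degrades, was 0.189 ± 0.0481 in HE (SD, n = 10) and 0.197 ± 0.0797 in LE (SD, n = 9; exact permutation p = 0.780). The actin pair gave exact p = 0.605 and the GAPDH pair 0.946.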

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

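No test in this part was chosen before the result was seen except the gap measure itself; the tests on BOLA-DQ probe sets were chosen after.

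Values far from the rest of their group were sought among the genes, list scores, components and probe sets named here, by the gap between the extreme steer and its neighbour relative to the range of the group. Of 240 groups of values, 28 held such a steer. Chance gives about 1 in 20 groups, or 12 of 240, if the groups are independent and not picked for their values; here list scores share members with named genes, and SERPINI2, XDH and the BOLA-DQ probe sets were picked after their values were seen, so the excess was not tested. LE steer 14 accounted for 7 of them and HE steer 2 for 6. LE steer 14 was lowest of its group for PSAT1 (13.8), IGF1 (7.04), CYP2E1 (14.008), CYP2C87 (6.56), ADH4 (14.4) and the score of the P450 and phase I list (-0.470), and highest for XDH, xanthine dehydrogenase (14.6). HE steer 2 was highest for ALDH18A1 (10.7), UQCR10 (11.8) and SRXN1 (9.10), and lowest for IGF1 (6.80), PRLR (11.9) and CYP2E1 (13.969). No explanation of these values was tested.

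Another 10 steers stood apart in 1 or 2 values each, and 7 in none. Low extremes were LTB in HE steer 1 (5.16), PRODH in HE steer 9 (2.85), GPT in HE steer 10 (2.11), CYP3A28 in HE steer 6 (11.7) and in LE steer 5 (12.1), RPS10 in LE steer 18 (13.5) and GCLC in LE steer 8 (6.78). High extremes were SPARC in HE steer 10 (10.4), PRODH (5.62) and COL1A2 (10.8) in LE steer 19, SLC25A20 in LE steer 8 (12.1), CD2 in LE steer 7 (5.06) and SERPINI2, a serpin gene, in LE steer 7 (13.1).

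In HE steer 16 the probe sets of BOLA-DQA5 (9.06) and BOLA-DQB (6.36), MHC class II genes, stood far above the other HE steers. Over all 19 steers BOLA-DQA5 was high in 4 (LE steers 5, 7 and 19 and HE steer 16; 9.06 to 9.87) and low in the rest (2.14 to 2.29), and the same 4 were high on BOLA-DQB (6.36 to 8.58 against 1.75 to 1.84; exact one-sided Fisher p = 0.000258). One probe set of BOLA-DQA2 and 1 of the 5 of BOLA-DQB1 were likewise high in the same 10 steers, 7 HE and 3 LE (exact one-sided Fisher p = 1.08e-05). Inherited class II haplotypes are a candidate explanation for this sharing, and the pairs were picked for their wide spread, so it stays a hypothesis; a sequence difference under the probes and a difference in expression cannot be separated with these values. High steers were not shown to differ in number between groups (exact Fisher p = 0.303 for the first pair and 0.179 for the second, both 0.303 adjusted), and an effect of the pasture was not tested apart from this.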

How the results depend on the processing

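The exact permutation of list scores was the only test here chosen after the data were seen. The unnamed probe set kept its direction and its call in all 28 alternatives that contained it (log2 -2.72 to -3.09, adjusted p from 2.59e-05 to 0.000710). Apart from omissions of a steer, named genes gave 1754 alternative values, of which 1745 kept direction and side of the threshold, 3 came past it and 6 reversed; list shifts gave 593, of which 518 kept both, 44 lost the call, 11 gained it (bile acid 5, fatty acid oxidation 3, and serine, mitochondrial biogenesis and cholangiocyte 1 each) and 20 reversed. Omissions gave 3097 gene values (3069 kept, 8 came past, 20 reversed) and 874 list values (779 kept, 15 lost, 35 gained, 45 reversed). Of 163 named genes, 34 moved by over 1.5 times when some steer was left out. The cause of these changes was not tested unless stated.

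Probe sets past the threshold went from 1 to 0 with the filter at the median, which removes that probe set, to 2 with array weights and to 6 with the first residual component as covariate, which by construction leaves the differences as they were and only changes the residual spread; at an unadjusted p there were 1571. Those higher in HE went from 0 to 1 with that covariate and to 692 at an unadjusted p, and those lower from 1 to 0, 2, 5 and 879 in the same order. Genes went from 0 to 3 with array weights, 3 at an adjusted p of 0.10 and 797 at an unadjusted p. Lists went from 16 to 1 with an estimated correlation, 1 with fry and 1 by exact permutation. Leaving out 1 steer gave 1 to 7 probe sets (0 to 1 higher, 1 to 6 lower; most without LE steer 14), 0 to 3 genes, 14 to 20 lists (20 without LE steer 5) and 0 to 1 components.

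Lists that came past camera when a steer was left out were the proteasome (9 of 19 omissions: HE 3, 11, 16 and 17, LE 5, 7, 12, 14 and 19; lowest adjusted p 0.00969), bile acid (7: HE 6, 15, 16 and 17, LE 12, 13 and 14; 0.00648), serine (6: HE 2, 6 and 9, LE 4, 5 and 19; 0.0186), fatty acid oxidation (5: HE 6 and 15, LE 4, 12 and 14; 0.0332), mitochondrial biogenesis (HE 15 or LE 14, 0.0376), cell cycle (HE 2 or LE 7, 0.0414), cholangiocyte (LE 8 or 18, 0.0408), ergot target (LE 5, 0.0382) and neutrophil (LE 5, 0.0227) lists. With an estimated correlation these same lists gave adjusted p values of 0.386 to 0.791.

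The sign changed in the following cases, given as the value reached. Median centring turned glycolysis (0.0014), amino acid catabolism (0.0025), phase II (0.014), ergot targets (0.014), ADRA2A (0.0082) and DRD2 (0.0057). Quantile normalization turned cholesterol (-0.00072), fatty acid synthesis (-0.0044), ergot targets (0.0025) and ADRA2A (0.00049). Array weights turned drug transporters (-0.014), cholesterol (-0.061), fatty acid synthesis (-0.032), ergot targets (0.0015), G6PC1 (-0.11) and PRSS2 (-0.46, from 0.58). The mean of all probe sets turned phase II (0.00018), cholesterol (-0.00025), ergot targets (0.00079), B and plasma cells (-0.032) and ALB (-0.0023). The filter at the median turned glycolysis (0.0026) and cholangiocytes (0.032), that at the lower quartile ergot targets (0.013) and cholangiocytes (0.00017), and the 3' to 5' covariate phase II (0.0030).

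Over omissions of a steer the mean shift ran from -0.052 to 0.0064 for glycolysis, -0.047 to 0.020 for amino acid catabolism, -0.039 to 0.042 for phase II, -0.017 to 0.071 for drug transporters, -0.071 to 0.058 for cholesterol and -0.051 to 0.031 for fatty acid synthesis. It ran from -0.060 to 0.0051 for complement, -0.0054 to 0.053 for GH and IGF, -0.022 to 0.0091 for ergot targets, -0.016 to 0.13 for the cell cycle, -0.014 to 0.062 for B and plasma cells and -0.093 to 0.13 for immediate early genes. Among genes it ran from -0.33 to 0.15 for CYP3A28, -0.11 to 0.13 for G6PC1, -0.018 to 0.081 for GOT2, -0.28 to 0.087 for HTR2B, -1.06 to 0.15 for GPX3 (all steers -0.65; positive without LE steer 8 or 14) and -0.036 to 1.18 for PRSS2 (negative without LE steer 7, 12 or 14). The 3' to 5' difference between groups ran from -0.028 to 0.0062, positive without LE steer 8 or HE steer 9; median centring cannot move it, being a difference within an array.

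No paired analysis was possible because each steer number occurs in only 1 group. The 2 alternatives planned for linear values were not run, since the values are log2. Signal near the floor limits what dim genes can show: only 7 of the 19 T and NK cell markers and 4 of the 20 ergot target genes reach the median probe set.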

Other observations

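Tests in this part chosen only after the result was seen were those of residual blood and of all leukocytes. The same holds for the splits for the T and NK cell and ribosomal lists and for the largest t of a probe set. The variable genes, the chaperone correlations and the exact permutation of list scores were also chosen after the data were seen.

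Some genes measured in these liver samples varied widely between steers. Haptoglobin (HP), an acute phase protein, ranged from 7.81 to 16.4 and averaged 13.9 ± 1.78 in HE (SD, n = 10) and 11.7 ± 3.28 in LE (SD, n = 9), a difference of log2 2.15 (SE 1.11, adjusted p = 0.622). The glutathione peroxidase gene GPX3 ranged from 3.16 to 11.9, highest in LE steer 14, and FKBP5, a gene induced by glucocorticoids, from 2.70 to 9.69. PRSS2, a digestive protease gene of the pancreas, lay under 3 in 5 steers and reached 10.4 in LE steer 8, while SERPINI2 stood at 13.1 in LE steer 7 against at most 2.84 in the other 18. Of the 20 probe sets with the widest spread within groups, 8 name a BOLA gene and 8 have no single gene listed.

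The cytosolic and endoplasmic reticulum chaperone lists varied together between steers. Within LE (n = 9) Pearson's r was 0.885 (exact permutation p = 0.000714, adjusted 0.00143) and Spearman's rho 0.867 (exact permutation p = 0.00451, adjusted 0.00902), and r was 0.836 without the 2 steers farthest from the median. Within HE (n = 10) r was 0.656 (permutation p = 0.0361, adjusted 0.0361) and rho 0.515 (permutation p = 0.134, adjusted 0.134), and r fell to 0.266 without 2 steers, on which the relation in HE rests. The 2 lists share 0 genes, and these 2 relations were the only ones computed.

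The lower T and NK cell marker list in HE may reflect fewer of these lymphocytes in the liver sampled or a lower content of their transcripts. RNA integrity was not shown to differ: the mean 3' minus 5' difference was 0.189 in HE and 0.197 in LE (exact permutation p = 0.780). As covariate it could therefore hardly move the list, so the 97.6% of the mean difference kept (camera adjusted p = 4.93e-11) decides nothing further. Chance is argued against but not excluded: 1 of 100 splits of the steers, the real one, gave a mean as large (-0.31, highest other 0.25). The exact permutation p adjusted over all lists was 0.0209, and both tests were chosen after the data were seen. Residual blood stays open, because the erythroid list differed by -0.043 but all 8 of its genes lie below the median probe set, and so does a lower share of all leukocytes, because the 4 brighter B and plasma cell markers differed by -0.046 (95% interval -0.417 to 0.324) against -0.38 for the 7 brighter T and NK cell markers. Markers of other leukocytes were also mostly lower: 11 of 12 for Kupffer cells or macrophages and all 13 for neutrophils. Of the neutrophil markers only 2 reach the median probe set, and neither list passed with an estimated correlation. The pasture is the biological difference in the design and stays untested, as each group had a single one.

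The higher cytosolic ribosomal protein list could be a shift of all abundant transcripts left by the normalization. Lists matched on mean expression had a median of -0.0025 against 0.0952 for this list, which argues against that. Its median also lay above the highest of 10000 matched lists (0.0672). That rank decides little, because matched genes were drawn independently while the ribosomal genes varied together (estimated correlation 0.513). With the 3' to 5' covariate 100.9% of the mean difference was kept (camera adjusted p = 1.70e-20). That covariate hardly differed between the groups, so this run decides nothing about RNA integrity. Of 100 splits, 3 gave a mean as large in size as the real 0.11 (highest other -0.13), but the list was picked from 46 after its result was seen, and its exact permutation p of 0.0105 became 0.111 adjusted over all lists, so chance is not excluded. A difference of the pastures stays open and untested.

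Splits of the steers into 10 and 9 also bear on the counts. For the probe set past the threshold chance is argued against by its size. Of 100 splits only the real one gave a largest absolute moderated t over all probe sets of 10.2 (highest other 7.66). This test was chosen after the result was seen, and 100 splits cannot exclude chance. The mere counts do not argue against chance. At least 1 probe set past the threshold came from 5 splits (highest other 2123). At least the real 16 lists came from 21 splits (highest other 21, median of the other 99 splits 11). For genes the splits decide nothing, because the real count of 0 is reached by all 100 (highest other 4). At an unadjusted p under 0.05, 13 gave as many probe sets as the real 1571 (highest other 6989). The split with 2123 probe sets, the one of the 100 with the most, points to a structure among the arrays that does not follow the pasture, whose source was not tested: 69.2% of its calls lie below the 25th percentile of brightness, with a median size of 0.060 on the log2 scale, and 5 HE steers are in its group of 10.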
